A study of Drosophila melanogaster with 39 samples.

How the data were processed

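Each of the 39 arrays compared 2 amplified RNA samples of Drosophila melanogaster imaginal discs, per the labels. RNA was amplified in linear rounds, coupled to Cy3 or Cy5 and hybridised to spotted arrays of gene probes. The deposited values are log2 ratios of the second-named over the first-named sample of each array, per the labels, which state the ratio and not its log base. The base was taken from the values, which lie around 0 and reach 17.08 in size. How the authors filtered and normalised them is not given in the sources used here. The medians of the deposited columns lie between -0.1143 and 0.2134, and each array was re-centred on its median. All ratios were turned so that a positive value means more transcript in the first-named sample. An array held values for 18.15 to 89.54 percent of the gene probes, and since no spot intensities were used, signal over background is unknown.

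Of 16505 probes, 144 were control spots. The probe names were matched to gene symbols through a table of release 6 of the genome assembly, 12612 by a current locus tag, 2720 by an older tag and 34 by symbol. Another 486 probes matched several genes and 509 none, and both kinds stayed unnamed. The 15366 named probes stand for 11436 genes, 2323 of them with more than 1 probe. For named genes and gene lists the probe with the most values stands for its gene. Probes whose names share a gene number had a median correlation over arrays of 0.853 in 1311 pairs, against 0.0229 in random pairs.

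Arrays were grouped by the comparison their labels name, with wing against leg split by leg segment, which gave 11 coefficients. The series describes the arrays of a category as independent replicates, and whether extracts are shared between categories is not stated. Each probe was fitted by least squares on all 39 arrays with these coefficients and a term for the dye orientation. Its variance was then moderated with the eBayes function of limma 3.58.1 (prior degrees of freedom 3.57, prior SD 0.2793) in R 4.3.3 with data.table (version 1.17.8). The least-squares step was written out instead of using lmFit as planned, so that contrasts stay exact where values are missing. Comparisons between categories were contrasts in the same fit. A probe was tested where at least 66.7 percent, and at least 2, of the arrays of each category had a value. The p-values are two-sided, were adjusted by the Benjamini-Hochberg method over the probes tested in a comparison, and were called at 0.05. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

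Before the data were examined, 31 gene lists of patterning, signalling, growth and tissue markers were written, and the labels of the samples, the tests and the alternatives were set. Some genes stand in several lists, so calls of different lists are not independent. Lists with at least 4 measured genes were tested with limma's cameraPR at a preset correlation of 0.01, and again with a correlation estimated from the residuals of probes sharing at least 10 arrays. Overlaps of called genes were tested with a two-sided Fisher exact test and adjusted over the overlaps tested. Which lists are described was decided with their results in view, and the Polycomb and trithorax group lists are described because of what is known of the study's question.

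Named genes follow a rule set before the data were examined. In each comparison they are the called genes with a symbol other than a CG or CR number, a value on every array and the same sign on all of them, the 8 highest and 8 lowest in the main comparisons and the 4 highest and 4 lowest in the others. Genes known only by such a number may have larger changes and are left out by this rule. In comparisons between categories, the same-sign condition was read as a value on every array and no overlap between the arrays of both categories. Reporter genes of each comparison are given whatever their values where enough arrays measured them, and up to 4 members of a described list with the smallest p in it. Cpr64Aa and the genes called in the dorsal-ventral difference beyond the rule were named after their values were seen.

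The test was tested on simulated data with 200 changed probes per comparison. A log2 change of 0.5 was recovered for 56 percent of the probes carrying it in wing against leg discs, 36 percent in Wg-expressing discs against the reference, 10 percent in TD against D(wg) cells and 46 percent in TD against V(wg) cells, so a gene that did not pass may still differ by that much. A log2 change of 1 was recovered for 100 percent of the probes carrying it in wing against leg discs, 80 percent in Wg-expressing discs against the reference, 72 percent in TD against D(wg) cells and 82 percent in TD against V(wg) cells. Of the calls 4.8, 4.3, 9.3 and 4.8 percent were false, and 0 probes were called with no change simulated. The simulated noise was normal and independent between probes, with 1 spread per probe on all arrays. The SD of the real arrays runs from 0.318 to 1.13, and probes may vary together, so these rates need not hold in the data.

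The alternatives were no dye term, each comparison fitted on its own arrays without the dye term, values not re-centred, scaled array spread, stricter and looser coverage, probes of a gene averaged, the slides of a single series, the sign turned on the arrays whose first-named sample is probe 2, and each array left out in turn. Where leaving one out left 1 array, it was assumed to vary like those of the other categories. The spread was scaled with limma's normalizeMedianAbsValues on centred arrays, since the scale method of normalizeBetweenArrays set before divides a plain matrix by medians, which lie near 0 here. The replacement is the function that this method applies to ratio objects, and it was chosen after the first output was seen. The sign of the arrays of TD against D(wt) was also turned, for genes and gene lists, an alternative added after the data were examined. So were the arrays of wing against leg discs left out in turn, which had been planned for smaller categories and the leg segments, and vg taken out of lists that hold it. Precision is limited by the number of arrays, 2 to 9 per category, and by the probes without a value. Raw images, spot intensities and alternative normalizations of them were not analysed here.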

Results

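Leg discs of Drosophila melanogaster larvae that are made to express the signalling protein Wingless (Wg) throughout can switch some of their cells from a leg to a wing fate, a change called transdetermination. The arrays compared such cells with other disc cells, 2 samples on each of 39 arrays. Wild-type first leg discs were set against a pooled reference of leg discs of all 3 segments on 4 arrays, and wing discs against a leg disc of the same larva on 9 arrays, 3 for each leg segment. Wg-expressing first leg discs were set against the reference on 6 arrays. Wg was induced by heat shocks at 60 and 72 h, 3 days before the discs were taken, and the labels give no heat shock for the wild-type samples. Comparisons of Wg-expressing or TD samples with wild-type samples, fragments or the reference therefore cannot separate Wg from heat shock or stock. Transdetermining (TD) cells, dissected by the fluorescence of a GFP reporter driven by the vg boundary enhancer, were set against the remaining dorsal cells, D(wg), on 3 arrays and against ventral cells, V(wg), on 5. D(wg) was set against V(wg) on 3 arrays, TD cells against dorsal cells of wild-type discs, D(wt), on 2, and D(wt) against ventral wild-type cells, V(wt), on 3. Regenerating fragments of second leg discs, cultured for 3 to 5 days in adult females, were set against the reference on 4 arrays. The arrays held between 2969 and 14650 values each, and the number of arrays limits the precision. All values are log2 ratios of the first-named over the second-named sample, with the standard error (SE) of the fit. All adjusted p-values are from limma. The variance behind each SE was pooled over the values of its probe on all 39 arrays. An SE therefore does not measure the spread within its own comparison. H15 in D(wt) against V(wt) lay at -1.26, -1.42 and -1.83 on the arrays, with an SE of 0.59. The probe chosen for wg had an SD of 1.04 over the 4 arrays of fragments, with an SE of 0.30.

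The comparison of wing with leg discs asked which genes tell the normal discs apart. The wing disc held far more transcript of vg, the wing selector gene (5.63 ± 0.39, SE, with values on 8 of 9 arrays), of ap, which specifies the dorsal wing compartment (3.49 ± 0.21, n = 9), and of the homeobox genes pdm2 (3.00 ± 0.30) and Dr (2.98 ± 0.21). The aquaporin gene Drip (2.69 ± 0.20), the integrin gene if (2.56 ± 0.17), the cuticle protein gene Cpr78E (2.56 ± 0.31), eya (2.35 ± 0.16) and Phk-3 (2.33 ± 0.28) were also higher in wing discs. The leg discs held more of the transcription factor genes gsb (-5.07 ± 0.31), unc-4 (-4.80 ± 0.30), lbl (-4.61 ± 0.14) and H15, which acts in the ventral leg (-2.73 ± 0.34), of the odorant-binding protein gene Obp99a (-3.55 ± 0.20), of rho (-1.89 ± 0.20) and pxb (-1.89 ± 0.14), and of the protease gene spirit (-1.87 ± 0.27). Dll, the distal leg selector, was lower in wing discs (-0.98 ± 0.14), while nub (-0.07 ± 0.07) and Antp (0.07 ± 0.22) did not pass the test. The values of nub lie between -0.20 and 0.14 in the comparisons that name it, so whether its probe responds to the transcript is not known.

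Of 25 measured wing fate genes, 15 were higher and 2 lower in wing discs, or 17 and 4 adjusted over the list alone, and the list as a whole was higher (adjusted p = 1.35e-31). Of 9 dorsal leg genes 5 were higher in wing discs and none lower, or 7 adjusted over the list alone. They included Doc1 (1.75 ± 0.18), Doc2 (1.73 ± 0.18) and Doc3 (1.43 ± 0.11), T-box genes, and the list was higher (adjusted p = 3.2e-15). Of 10 ventral leg genes 4 were lower and none higher, the same number adjusted over the list alone, among them Lim1 (-3.86 ± 0.36) and Wnt6 (-0.88 ± 0.14), and the list was lower (adjusted p = 5.33e-06). These 3 calls held with a correlation estimated from the residuals. They are not independent, since the lists share members. As written, pnr, ara and caup are in the wing fate and dorsal leg lists, and Wnt6 is in the wing fate and ventral leg lists. The lists were not tested without these genes. Of 21 Notch pathway genes 6 were lower and 1 higher, or 6 and 2 adjusted over the list alone, led by E(spl)mgamma-HLH (-1.26 ± 0.20) and Ocho (-0.88 ± 0.12), with adjusted p = 0.00283 for the list. This call was lost (adjusted p = 0.453 with an estimated correlation). In all 301 of 6648 probes passed, 170 higher and 131 lower, against 619 with scaled array spread and 179 with values on every array. Scr, the Hox gene of the first leg segment, was lower in wing discs (-0.52 ± 0.15), a call lost on the slides of 1 series (-0.28) and on the arrays of this comparison alone without the dye term, where the value stayed at -0.52 (adjusted p = 0.309). It was also lost without replicate 2, 3, 4, 6, 8 or 9 (-0.55 to -0.30). Leaving out 1 array gave 216 to 259 probes.

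**Figure D1:**
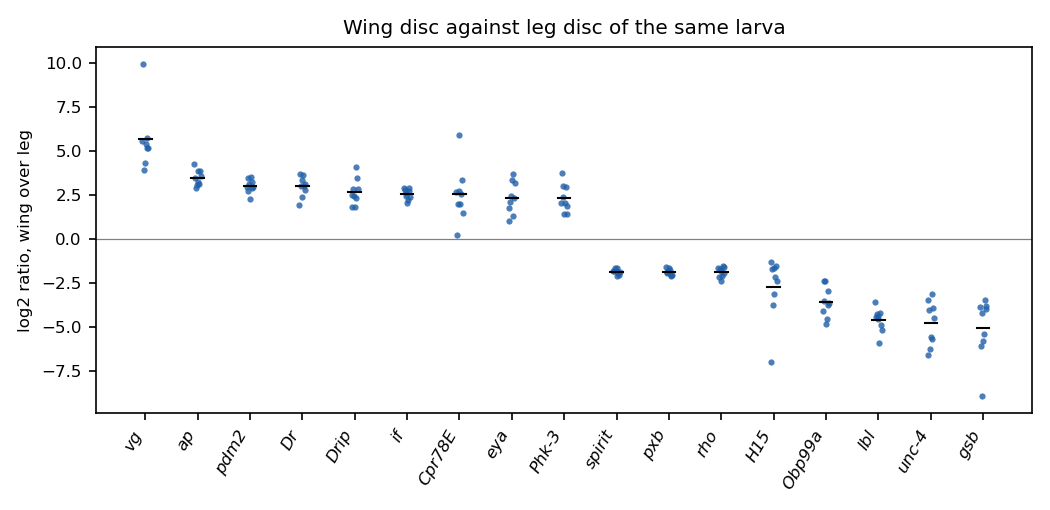
Log2 ratio of wing over leg disc for 17 genes. Points are arrays, 9 in all, and bars are their means. vg, ap and pdm2 lie above 0 and gsb, unc-4 and lbl below 0 on each array with a value.

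The leg segments were each compared through the wing disc of the same larva, and 1 probe passed in the 3 comparisons. Scr stood 1.40 ± 0.34 higher in first than in second leg discs and 1.38 ± 0.38 higher than in leg discs of segment 3, and neither difference passed (adjusted p = 0.59 and 0.9). Without replicate 1 of wing against leg discs, Scr passed in first against second leg (1.85, adjusted p = 0.0154). First against second leg gave 1 probe, that of the cuticle gene Cpr64Aa (-2.28, adjusted p = 0.0233), named after its value was seen. Of the other reporters none passed in any of the 3 comparisons. vg stood at -2.39 ± 0.90 in segment 1 against 2, -1.69 ± 0.99 in 1 against 3 and 0.70 ± 0.99 in 2 against 3, Antp at 0.05 ± 0.55, 0.30 ± 0.55 and 0.25 ± 0.55, Dll at 0.18 ± 0.33, -0.07 ± 0.33 and -0.25 ± 0.33, ap at -0.32 ± 0.53, -0.03 ± 0.52 and 0.29 ± 0.53, and nub at 0.14 ± 0.18, -0.06 ± 0.16 and -0.20 ± 0.18. Scr in segment 2 against 3 was -0.02 ± 0.38, and dac, measured for 1 against 2 alone, was -0.52 ± 0.24. The limma test gave 0 probes for segment 1 against 3 and 0 for 2 against 3, with 56 and 59 probes at an unadjusted p under 0.05. The Hox list was higher in segment 1 than in 3 (adjusted p = 0.00197, and adjusted p = 0.0278 with an estimated correlation), with 7 genes measured and none passing, or 1 adjusted over the list alone. The other lists called held no passing gene and were lost with an estimated correlation. They were myoblast markers, lower in segment 1 than in 2 (adjusted p = 0.023 and 0.675), Notch pathway genes, higher in 1 than in 3 (adjusted p = 0.0199 and 0.968) and in 2 than in 3 (adjusted p = 0.0153 and 0.701), cuticle genes, lower in both (adjusted p = 0.00392 and 0.176, and adjusted p = 0.0178 and 0.701), and cytosolic ribosomal proteins, lower in 2 than in 3 (adjusted p = 0.0153 and 0.961).

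The wild-type first leg disc was set against the leg reference as a control. It held much less transcript of the fat body genes Lsp1gamma (-4.01 ± 0.17, n = 4) and Lsp2 (-3.42 ± 0.12), which encode storage proteins of the larval blood, of Fbp2 (-2.90 ± 0.21), and of the muscle myosin gene Mhc (-3.82 ± 0.42). More transcript was found of the RNA-binding protein gene stau (1.61 ± 0.24), of COX7C (1.55 ± 0.36), a respiratory chain gene, of RpS9 (1.43 ± 0.22), which encodes a ribosomal protein, and of the splicing gene SNRPG (1.40 ± 0.20). puc, a target of JNK signalling, did not pass (0.27 ± 0.41). Of 12 larval fat body markers 7 were lower and none higher, the same adjusted over the list alone, and the list was lower (adjusted p = 3.96e-37), which held with an estimated correlation. Of 83 cytosolic ribosomal protein genes 43 were higher and none lower, or 50 adjusted over the list alone. That list was higher (adjusted p = 1.91e-17), a call lost with residual correlation (adjusted p = 0.848 with an estimated correlation). In all 1412 of 7912 probes passed, 615 higher and 797 lower. On this comparison's arrays alone without the dye term 422 passed, and 335 or 334 without replicate 1 or 2. With the probes of a gene averaged, stau fell short of the threshold (0.46), as COX7C did without replicate 2 (1.31).

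Wg-expressing first leg discs were compared with the leg reference. They held more of Reepl1 (6.07 ± 0.36, n = 6), of w (5.85 ± 0.61), the eye colour transporter gene that also marks many transgenes, of Ilp8 (5.70 ± 0.72), an insulin-like hormone that growing or damaged discs release and that delays metamorphosis, and of t (4.44 ± 0.23). Also higher were Cyp18a1 (4.00 ± 0.46), whose enzyme breaks down the moulting hormone, the serpin gene Spn47C (3.63 ± 0.22), Culd (3.54 ± 0.22) and mthl8 (2.89 ± 0.19). Lower were the cytochrome gene Cyp6t3 (-3.29 ± 0.37), the sugar transporter gene sut2 (-2.92 ± 0.30), the cuticle gene Lcp1 (-2.57 ± 0.31), fok (-2.53 ± 0.26), the receptor gene drl (-2.39 ± 0.17), the RNA-binding gene Imp (-2.36 ± 0.32), RN-tre (-2.35 ± 0.38) and the muscle actin gene Act57B (-2.21 ± 0.34). The wg probe chosen for the gene gave -0.64 ± 0.25 and missed the threshold (adjusted p = 0.063), while the other wg probe was higher (1.36 ± 0.22, adjusted p = 4.31e-05). The chosen probe passed on these arrays alone without the dye term (-0.64), and the average of both probes stood at 0.36. puc did not pass (0.41 ± 0.33). The dorsal leg list had 12 measured genes, 8 lower and 1 higher, the same adjusted over the list alone, including Doc2 (-2.18 ± 0.22) and Doc1 (-1.68 ± 0.23). The list was lower (adjusted p = 0.00366), but not with residual correlation (adjusted p = 0.305 with an estimated correlation). Of 29 Notch pathway genes 13 were lower and none higher, or 14 adjusted over the list alone, with Ocho at -0.81 ± 0.14 and E(spl)m8-HLH at -0.94 ± 0.17 (adjusted p = 0.00366 for the list, and adjusted p = 0.558 with an estimated correlation). In all 2587 of 12253 probes passed, 1237 higher and 1350 lower, and 1625 passed without replicate 1.

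These discs were also set against the wild-type first leg disc through the reference. No slide series holds both kinds of disc, so every difference here is confounded with the slide series. Wg-expressing discs were higher in Cyp18a1 (4.34 ± 0.74), in Cralbp (2.35 ± 0.43), in the prolyl hydroxylase gene Hph (2.12 ± 0.20) and in yellow-e3 (2.04 ± 0.31). They were lower in RN-tre (-3.20 ± 0.61), Imp (-2.17 ± 0.50), heca (-1.91 ± 0.47) and the guidance gene NetA (-1.75 ± 0.34). puc (0.14 ± 0.53) did not pass, nor did wg by its chosen probe (-0.68 ± 0.39). The average of both wg probes gave 0.28, and against the reference the other probe stood at 1.36 in Wg-expressing and 0.12 in wild-type discs. Fat body markers were higher, with Lsp1gamma at 4.30 ± 0.22, Lsp2 at 3.31 ± 0.19 and Fbp2 at 2.96 ± 0.31. Of 12 markers 6 were higher and none lower, or 7 adjusted over the list alone, and the list was higher (adjusted p = 1.47e-24), which held with an estimated correlation. Of 25 Notch pathway genes 8 were lower and none higher, or 14 adjusted over the list alone, among them dpn (-0.71 ± 0.14) (adjusted p = 3.29e-06 for the list, and adjusted p = 0.108 with an estimated correlation). In all 518 of 7799 probes passed, 273 higher and 245 lower, against 270 on these arrays alone without the dye term, 260 with scaled array spread, and 232 and 264 without replicates 1 and 2 of the wild-type discs. The heca call ended without either of these replicates (-1.62 and -1.77), and that of NetA with scaled spread (-1.54).

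**Figure D2:**
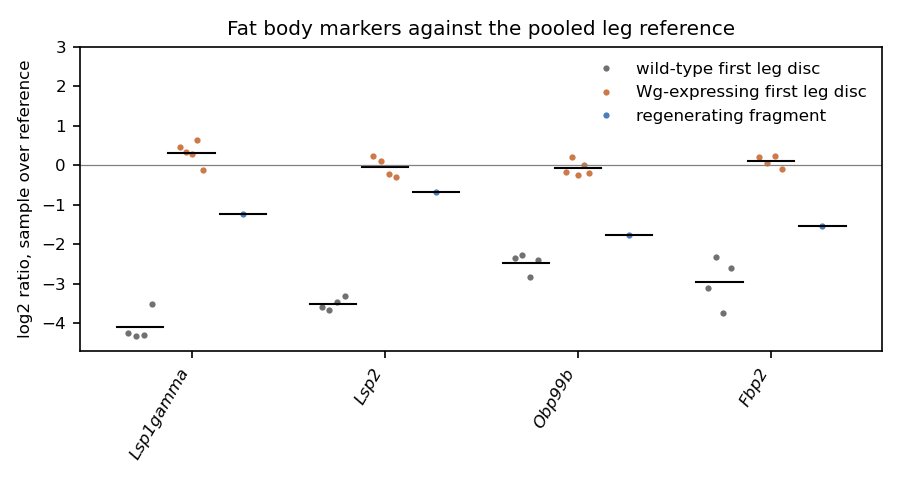
Log2 ratio of each sample over the leg reference for 4 fat body genes. Points are arrays and bars are means, and the fragments have a value on 1 array. Lsp1gamma lies between -4.32 and -3.50 on the 4 arrays of wild-type first leg discs and between -0.12 and 0.64 on the 5 arrays of Wg-expressing discs with a value.

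TD cells were compared with the other dorsal cells of the same discs. TD cells held more of Ama, an adhesion molecule gene of the Antennapedia complex (2.56 ± 0.25, n = 3), of slow (2.38 ± 0.45), of upd1, which encodes a JAK/STAT ligand (2.31 ± 0.43), of SP1173 (1.98 ± 0.41), Spn47C (1.97 ± 0.31), the chaperone gene Hsp83 (1.95 ± 0.59), the matrix metalloproteinase gene Mmp1 (1.89 ± 0.32) and lost (1.87 ± 0.65). vg was higher (3.76 ± 0.77, with values on 2 of 3 arrays), but the cells were chosen by a reporter of its enhancer, so this is no independent finding. TD cells held less of the chitin-binding protein gene obst-A (-3.46 ± 0.38), the sulfotransferase gene St2 (-2.90 ± 0.49), heca (-2.44 ± 0.42), the kinase gene nmo (-2.20 ± 0.49), Pepck1 of glucose synthesis (-2.17 ± 0.71), the GATA factor gene grn (-2.08 ± 0.43), Tis11 (-1.90 ± 0.46) and Os-C (-1.89 ± 0.41). Dll was lower (-1.03 ± 0.23), and wg (0.04 ± 0.35), nub (0.09 ± 0.11) and ap (-0.36 ± 0.37) did not pass. Without a single array, the calls of Hsp83, lost and Pepck1 ended whichever array was left out (1.44 to 2.27, 1.24 to 2.23 and -2.25 to -2.11), as did those of nmo and Tis11 without replicate 2 (-1.62 and -1.76). The Dll call ended with the probes of the gene averaged (-0.31, adjusted p = 0.54), and scaled spread ended those of vg (3.78) and Pepck1 (-1.88).

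Of 34 ribosome biogenesis genes 15 were higher in TD than in D(wg) cells and none lower, or 17 and 1 adjusted over the list alone, including Nnp-1 (1.31 ± 0.27) and pit (1.27 ± 0.28). The list was higher (adjusted p = 0.000672, and adjusted p = 0.336 with an estimated correlation). Of 16 genes of glycolysis and lactate 5 were lower and 1 higher, the same adjusted over the list alone, including the aldolase gene Ald1 (-1.67 ± 0.28) and Pgi (-1.50 ± 0.27) (adjusted p = 0.0114 for the list, and adjusted p = 0.086 with an estimated correlation). Of 27 Notch pathway genes 5 were lower and none higher, the same adjusted over the list alone, with E(spl)m7-HLH at -1.02 ± 0.22 (adjusted p = 0.00127 for the list, and adjusted p = 0.336 with an estimated correlation). Polycomb group genes, which keep other genes silent, did not move in a shared direction as a list (adjusted p = 0.179). The list test asks for a shared direction, so changes both ways do not pass it. Of 21 measured Polycomb group genes 2 were higher and 5 lower, or 3 and 5 adjusted over the list alone, with Su(z)2 at -1.54 ± 0.30 and Pc at 0.67 ± 0.14. Of all 7066 genes tested in this comparison 1317 passed. Of 30 trithorax group genes 3 were higher and 5 lower, or 4 and 8 adjusted over the list alone (adjusted p = 0.346 for the list). In all 1640 of 9189 probes passed, 955 higher and 685 lower, whereas the values as deposited gave 755 higher and 881 lower. Without replicate 2 or 3 the count was 473 or 601, and without replicate 3 the calls of pit (1.06) and Nnp-1 (0.95) ended.

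TD cells were also compared with ventral cells of the same discs. They held more of Ilp8 (5.91 ± 0.79, n = 5), Cyp18a1 (4.06 ± 0.51), upd1 (3.93 ± 0.33), the acetylcholine receptor gene nAChRbeta3 (2.67 ± 0.29), the cuticle gene Edg91 (2.48 ± 0.61), Spn47C (2.46 ± 0.24), HBS1 (2.45 ± 0.57), Ama (2.37 ± 0.19) and Mmp1 (2.33 ± 0.25). They held less of wg (-3.21 ± 0.27, and -0.93 ± 0.24 by its other probe), St2 (-3.01 ± 0.38), the Wnt ligand gene Wnt6 (-2.84 ± 0.18), spirit (-2.79 ± 0.36), lbl (-2.76 ± 0.19), Had1 (-2.39 ± 0.20), obst-A (-2.32 ± 0.29) and the aquaporin gene Prip (-2.28 ± 0.40). vg was higher (3.59 ± 0.56, with values on 4 of 5 arrays), as the choice of cells sets, and Dll lower (-1.16 ± 0.18), while nub (-0.03 ± 0.09) and ap (-0.05 ± 0.29) did not pass. The Edg91 call ended without replicate 2 (1.97) and that of HBS1 on these arrays alone without the dye term (2.43).

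Of 9 ventral leg genes 6 were lower in TD than in V(wg) cells and none higher, or 8 adjusted over the list alone, including fz3 (-1.21 ± 0.17) and Wnt4 (-1.07 ± 0.21), and the list was lower (adjusted p = 5.31e-14). Of 15 genes of glycolysis and lactate 6 were lower and none higher, or 7 adjusted over the list alone, with Tpi at -1.65 ± 0.24 and Ald1 at -1.59 ± 0.21 (adjusted p = 0.000209 for the list). Both calls held with an estimated correlation. So did a call for 9 genes of the Hox list (adjusted p = 0.0131), in which 2 were higher and none lower, the same adjusted over the list alone. These were Ama, which is not a homeobox gene, and exd (1.44 ± 0.33), a cofactor of Hox proteins whose call ended without replicate 1 (1.10). Of 49 cell cycle genes 13 were higher and none lower, or 18 adjusted over the list alone, with the primase gene Prim1 at 1.33 ± 0.18 (adjusted p = 8.53e-05 for the list, and adjusted p = 0.227 with an estimated correlation). Of 33 ribosome biogenesis genes 9 were higher and none lower, the same adjusted over the list alone, including Ns1 (1.63 ± 0.32) (adjusted p = 4.32e-05 for the list, and adjusted p = 0.182 with an estimated correlation). Of 25 wing fate genes 3 were higher, vg and Dr (1.99 ± 0.28) among them, and 6 lower, with Ser at -1.32 ± 0.18, the same adjusted over the list alone. The list was lower (adjusted p = 0.0409, and adjusted p = 0.496 with an estimated correlation), also without vg, whose value the choice of cells sets (adjusted p = 0.0084, and adjusted p = 0.258 with an estimated correlation). The 6 lower genes include Wnt6 (-2.84), which is also in the ventral leg list and was lower in wing than in leg discs (-0.88). The list was not tested without Wnt6, so its call does not show a loss of genes that are high in wing discs. In all 1171 of 8716 probes passed, 601 higher and 570 lower, against 385 on these arrays alone without the dye term and 577 without replicate 1. On these arrays alone without the dye term the calls of exd (1.41) and Ns1 (1.60) ended.

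**Figure D3:**
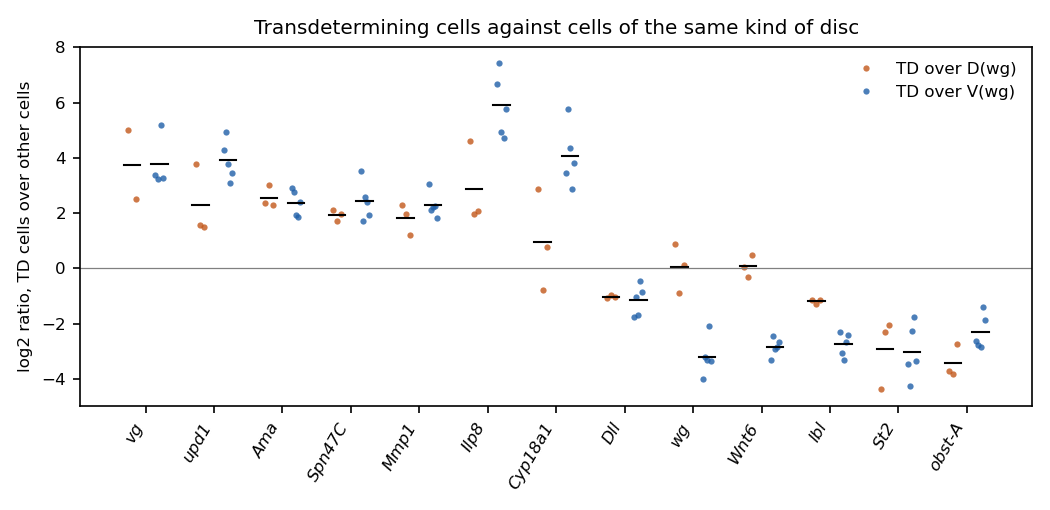
Log2 ratio of TD cells over D(wg) and over V(wg) cells for 13 genes. Points are arrays and bars are means. vg, upd1 and Ama lie above 0 and obst-A and St2 below 0 in both comparisons.

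Dorsal and ventral cells of wild-type discs differed in patterning genes. The dorsal cells held less of wg (-4.56 ± 0.35, n = 3), Wnt6 (-3.62 ± 0.24), lbl (-3.28 ± 0.24) and the Wg receptor gene fz3 (-2.46 ± 0.22). They held more of Ance (3.19 ± 0.54), a peptidase gene, opa (2.88 ± 0.29), a zinc finger factor gene, Obp99a (2.37 ± 0.34), Obp56a (2.13 ± 0.47), Doc1 (2.04 ± 0.30) and Doc3 (1.32 ± 0.18). dpp, the dorsal signal of the leg disc, stood at 1.00 ± 0.30 and did not pass (adjusted p = 0.26), nor did H15 (-1.44 ± 0.59), mid (-0.02 ± 0.14) or Doc2 (0.98 ± 0.38). These calls depend on the setting, since on these arrays alone without the dye term H15 (-1.50, adjusted p = 3.92e-11), dpp (1.00, adjusted p = 1.06e-06) and Doc2 (0.98, adjusted p = 0.000125) passed, and dpp (1.60) and Doc2 (1.66) with scaled spread. Of 9 ventral leg genes 3 were lower and none higher, or 4 adjusted over the list alone (adjusted p = 4.3e-47 for the list), and of 10 dorsal leg genes 2 were higher and none lower, or 5 adjusted over the list alone (adjusted p = 9.27e-15 for the list). Both calls held with an estimated correlation. In all 50 of 7207 probes passed, 26 higher and 24 lower, against 223 on these arrays alone without the dye term and 165 with scaled array spread. Without replicate 2 or 3 the count was 19 or 20, and the Obp56a call ended (1.78 and 1.82).

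In Wg-expressing discs the dorsal cells again held less of wg (-3.86 ± 0.35, n = 3), Wnt6 (-2.57 ± 0.24) and lbl (-1.83 ± 0.24), and of the receptor gene mth (-1.68 ± 0.34). The 2 named genes higher in dorsal cells were Tfb4 (0.62 ± 0.14) and Pu (0.41 ± 0.09), whose calls ended without replicate 1 (0.67 and 0.48) or 2 (0.45 and 0.39), as did that of mth (-1.68 and -1.46), and that of Pu without replicate 3 (0.38). The calls of Tfb4 and Pu also ended without the dye term (0.65 and 0.41), as deposited (0.63 and 0.41), with scaled spread (0.56 and 0.41) and with averaged probes (0.62 and 0.13). That of mth ended on these arrays alone without the dye term (-1.70), as theirs did, and that of lbl with scaled spread (-1.76, adjusted p = 0.146). The other wg probe gave -1.16 ± 0.31 and did not pass (adjusted p = 0.0828). Doc1 (0.31 ± 0.30), Doc3 (-0.05 ± 0.18), dpp (-0.66 ± 0.30), H15 (-0.10 ± 0.59), mid (0.34 ± 0.14) and bi (0.25 ± 0.12) did not pass, although dpp did without replicate 3 (-1.26). Called lists were ventral leg genes (adjusted p = 0.00338) and Wg signalling (adjusted p = 0.0142), both lower, and hemocyte markers (adjusted p = 0.0341) and cytosolic (adjusted p = 4.85e-06) and mitochondrial ribosomal proteins (adjusted p = 1.41e-05), higher. None held with an estimated correlation (adjusted p = 0.25 for ventral leg genes and at least 0.709 for the others). The ventral leg and Wg signalling lists share wg, Wnt6, fz3 and other members. Between the kinds of disc the dorsal samples are unlike. D(wg) cells are those remaining beside the TD cells, while D(wt) cells are dorsal cells of wild-type discs. How much of the differences below comes from this was not tested. The dorsal-ventral ratio differed between Wg-expressing and wild-type discs for opa (-2.78 ± 0.41), Doc3 (-1.37 ± 0.26) and fz3 (1.83 ± 0.31), and the Doc3 call ended without replicate 1 of either kind of disc (-1.23 and -1.37) or replicate 3 (-1.40 and -1.29). The opa call ended on these arrays alone without the dye term (-2.75, adjusted p = 0.169). It did not pass for wg (0.70 ± 0.50), dpp (-1.66 ± 0.43), Doc1 (-1.73 ± 0.42), H15 (1.34 ± 0.84) or mid (0.36 ± 0.21). With scaled spread wg (3.70, adjusted p = 0.00941), dpp (-1.99, adjusted p = 0.0334) and Doc1 (-3.06, adjusted p = 0.00132) passed. Doc1 also passed on these arrays alone without the dye term (-1.81), dpp without replicate 3 of the Wg-expressing discs (-2.24), and the other wg probe passed at 2.85 (adjusted p = 0.000596). The ventral leg list moved toward 0 in Wg-expressing discs, as a positive difference (adjusted p = 0.000114, which held with an estimated correlation), with 1 of 9 genes passing, or 2 adjusted over the list alone. In all 25 of 9399 probes passed in Wg-expressing discs, 7 higher and 18 lower, against 9 with scaled array spread, 11 without replicate 2 and 322 without replicate 3. The difference itself gave 8 of 6929 probes, 5 higher and 3 lower, against 21 and 33 with scaled array spread.

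**Figure D4:**
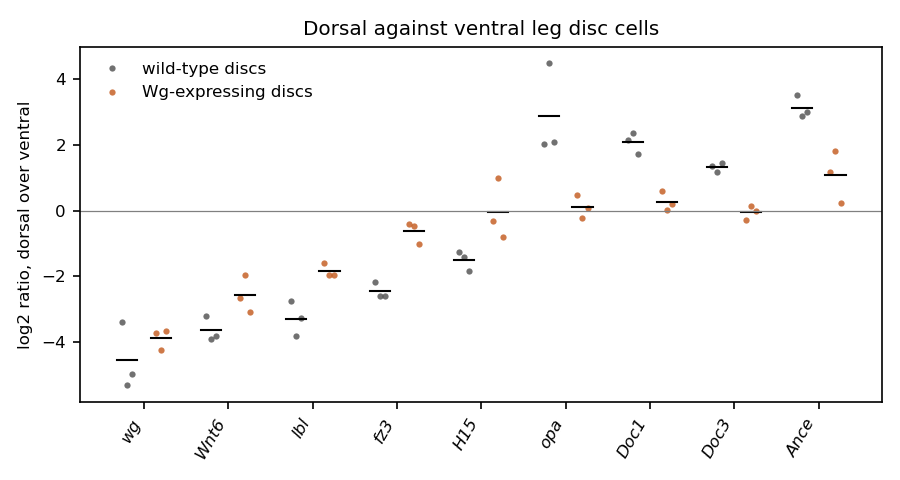
Log2 ratio of dorsal over ventral leg disc cells for 9 genes in wild-type and Wg-expressing discs. Points are arrays, 3 for each kind of disc, and bars are means. opa averages 2.88 in wild-type and 0.10 in Wg-expressing discs in the fit.

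On the arrays labelled TD against D(wt) the direction is unsettled. GFP control spots, for which the genotypes in the labels give a transcript in TD cells alone, had medians of -1.91 and -5.02 with the sign the labels give, and all values here keep that sign. Every GFP spot lay below 0 on both arrays (highest -1.26 and -1.77), which argues against the sign as labelled. Both arrays have TD cells as probe 2, so the dye term in these values is estimated from other categories. Lowest among the genes that the naming rule admits were w (-6.91 ± 1.10, n = 2), Ilp8 (-6.71 ± 1.32), Reepl1 (-4.15 ± 0.65) and t (-3.93 ± 0.41). The probe named wg stood at -4.73 ± 0.39, with the smallest adjusted p of this comparison (3.23e-09), and the other wg probe, with a value on 1 array (-0.27), was not tested. Highest by the same rule were the ecdysone-induced gene ImpE2 (3.66 ± 0.77), Obp56a (3.00 ± 0.59), Obp99a (2.95 ± 0.43) and drl (2.90 ± 0.31). vg did not pass (-1.40 ± 0.81, adjusted p = 0.3), nor did Dll (-0.55 ± 0.29), ap (-0.92 ± 0.47) or nub (-0.05 ± 0.14). On these arrays alone without the dye term vg (-1.75, adjusted p = 0.000706) and ap (-0.95, adjusted p = 0.0201) passed, and with the sign turned vg stood at 2.10 and did not pass. Of 23 Notch pathway genes 5 lay above 0 and passed, the same adjusted over the list alone, with E(spl)m7-HLH at 1.42 ± 0.27 (adjusted p = 0.00943 for the list, and adjusted p = 0.69 with an estimated correlation). With the sign turned the same number lay below 0, and the list was lower (adjusted p = 0.0078, and adjusted p = 0.958 with an estimated correlation), so its direction is as unsettled as the sign. That sign also gave calls for JAK/STAT (adjusted p = 0.0349) and ribosome biogenesis genes (adjusted p = 0.0163), higher, and cytosolic ribosomal proteins (adjusted p = 0.000427), lower. All were lost with an estimated correlation (adjusted p = 0.958). In all 729 of 7744 probes passed, 315 above and 414 below 0. The values as deposited gave 435 above and 311 below, and the sign turned on these arrays gave 637 probes, 279 above and 358 below. The largest count was 1518, with 789 above and 729 below, on these arrays alone without the dye term. Leaving out either array left 82 or 195, and ended the calls of Ilp8 (-6.31 and -7.11) and ImpE2 (3.51 and 3.81), and without replicate 1 those of Obp56a (2.87), Reepl1 (-3.86) and E(spl)m7-HLH (1.17). Scaled spread ended the call of Ilp8 as well (-5.75).

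Regenerating fragments were compared with the leg reference. They held more of the cuticle gene Cpr51A (4.37 ± 0.28, n = 4), of Thor, a repressor of translation (4.15 ± 0.47), of Osi2 (3.08 ± 0.34), Aldh (2.82 ± 0.54), regucalcin (2.68 ± 0.46), heca (2.62 ± 0.36), the transcription factor gene ken (2.42 ± 0.39) and Phk-3 (2.03 ± 0.41). They held less of the cuticle genes Cpr49Ac (-3.98 ± 0.67) and Lcp1 (-2.45 ± 0.37), of ImpE2 (-3.23 ± 0.53), wbl (-2.90 ± 0.34) and mnd (-2.42 ± 0.23), and of the chaperone genes Hsp83 (-3.04 ± 0.51), DnaJ-1 (-2.94 ± 0.49) and Hsp27 (-2.43 ± 0.27). Of 10 heat shock protein genes 7 were lower and none higher, the same adjusted over the list alone (adjusted p = 0.0138 for the list, and adjusted p = 0.849 with an estimated correlation). Of 22 ribosome biogenesis genes 11 were lower and none higher, or 12 adjusted over the list alone, including pit (-1.67 ± 0.24) and Fib (-1.39 ± 0.20) (adjusted p = 0.0138 for the list, and adjusted p = 0.849 with an estimated correlation). puc, a JNK target, did not pass (0.69 ± 0.40). In all 1579 of 3885 probes passed, 616 higher and 963 lower, against 426 on these arrays alone without the dye term and 514 with scaled array spread, a setting that ended the calls of regucalcin (1.62) and Phk-3 (1.16).

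Set against the wild-type first leg disc, the fragments were higher in Cpr51A (4.23 ± 0.40), regucalcin (3.05 ± 0.66), Nelf-A (2.20 ± 0.68) and the muscle factor gene Mef2 (2.05 ± 0.47), and lower in DnaJ-1 (-2.09 ± 0.70), wbl (-2.05 ± 0.49), mnd (-1.93 ± 0.33) and san (-1.90 ± 0.31). puc did not pass (0.41 ± 0.58). Here 755 of 3832 probes passed, 216 higher and 539 lower, against 116 with scaled array spread and 177 on these arrays alone without the dye term. Without replicate 1 of the wild-type discs or replicate 3 of the fragments, 491 and 493 passed, and the Nelf-A call ended without either (2.17 and 1.49). It also ended without replicate 2 of the wild-type discs (2.10), and that of DnaJ-1 without their replicate 4 (-1.18) or any 1 of the fragments (-2.23 to -1.96). With scaled spread the calls of regucalcin (1.97), Nelf-A (1.20), DnaJ-1 (-1.25), wbl (-0.99) and mnd (-1.01) ended. On these arrays alone without the dye term those of Nelf-A (2.09), Mef2 (2.02), DnaJ-1 (-2.10) and wbl (-2.08) did. Wg-expressing discs and fragments share no slide series either, so their differences are confounded with it as well. Wg-expressing discs, set against the fragments, were higher in mnd (2.33 ± 0.30), HnRNP-K (2.06 ± 0.43), fd96Cb (1.98 ± 0.52) and Sps1 (1.94 ± 0.25), and lower in Cpr51A (-4.85 ± 0.37), heca (-3.71 ± 0.47), Aldh (-3.44 ± 0.70) and regucalcin (-3.23 ± 0.59). With scaled spread the calls of fd96Cb (1.43) and regucalcin (-2.11) ended. wg (-0.75 ± 0.39) and puc (-0.27 ± 0.52) did not pass, although wg did without replicate 2 of the fragments (-1.22), and the average of both wg probes was 0.20. Of 22 ribosome biogenesis genes 13 were higher and none lower, or 15 adjusted over the list alone, including Fib (1.46 ± 0.25) (adjusted p = 0.000133 for the list, and adjusted p = 0.331 with an estimated correlation). In all 1046 of 3864 probes passed, 705 higher and 341 lower, against 331 with scaled array spread and 660 on these arrays alone without the dye term.

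Genes called in TD cells were compared with those called elsewhere, by a Fisher exact test on genes tested in both. Against wing discs, 30 genes were higher both in TD over V(wg) cells and in wing over leg discs, where independent lists would share 9.01 (adjusted p = 4.54e-09), and 40 were lower in both, where independent lists would share 7.54 (adjusted p = 2.28e-19). For TD over D(wg) cells the shared numbers were 23 against 14.3 (adjusted p = 0.0299) and 29 against 9.67 (adjusted p = 6.48e-08). vg, whose value the choice of cells sets, is among the shared higher genes. Genes higher in TD than in D(wg) cells and lower in wing discs numbered 4 against 12.07 (adjusted p = 0.012). The other way gave 11 against 11.45, which did not pass. For TD over V(wg) cells these were 3 against 7.51 and 6 against 9.05 (adjusted p = 0.105 and 0.41). TD cells are dorsal, so TD over V(wg) cells also sets dorsal against ventral position. Across genes, wing over leg discs correlated with dorsal over ventral cells at r = 0.233 in wild-type and -0.015 in Wg-expressing discs. How much of the overlap for TD over V(wg) cells comes from position was not tested. Against regenerating fragments most directions were opposed. Of the genes higher in TD than in D(wg) cells, 141 were lower in the fragments, where independent lists would share 58.92, and 6 were higher, where they would share 35.39 (adjusted p = 6.17e-32 and 3.38e-10). For TD over V(wg) cells these numbers were 90 against 53.12 (adjusted p = 1.67e-08) and 26 against 31.82, which did not pass (adjusted p = 0.306). The opposition is not particular to regeneration, since across genes TD over D(wg) cells correlated with the fragments at r = -0.382 and with wild-type first leg discs over the same reference at r = -0.503. D(wg) over V(wg) cells correlated with these at r = 0.319 and 0.472, and TD over V(wg) cells at r = -0.206 and -0.259. How much of the opposition comes from the D(wg) samples and not from TD cells was not tested. Wg-expressing discs over the reference shared 101 higher and 101 lower genes with TD over V(wg) cells, where independent lists would share 61.59 and 53.12 (adjusted p = 3.38e-07 and 1.25e-10). TD over D(wg) cells ran opposite. There 114 genes were higher in TD cells and lower in these discs against 85.4, and 101 the other way against 70.51 (adjusted p = 0.00131 and 0.000191). Same directions gave 78 against 96.73 and 53 against 62.25 (adjusted p = 0.0417 and 0.242). TD over D(wg) and TD over V(wg) cells shared 275 higher genes and 207 lower genes, where independent lists would share 50.38 and 37.85. Both comparisons may use the same TD extracts, and part of this excess may come from that. Genes are not independent replicates.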

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

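The tests of explanations and of other splits of the arrays in this part were chosen after the results were seen. A value is given here where 1 array lay far from the others of its category, where an effect differed between kinds of disc, or where spots outside the comparisons gave a signal. Of 98 sets of values looked at, 12 held an array far from the others, and chance gives about 1 in 20.

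On replicate 2 of the wing and leg discs, vg stood at 9.98 against 3.92 to 5.77 on the other arrays, H15 at -7.01 against -3.78 to -1.32, and Scr at -2.83 against -0.98 to 0.19. Replicate 4 had gsb at -8.97 against -6.11 to -3.46, and the SD of the log2 ratios on replicate 1 was 0.745 against 0.425 to 0.585. Among wild-type first leg discs, Lsp1gamma stood at -3.50 on replicate 4 and between -4.32 and -4.23 on the others. Among Wg-expressing discs, Lcp1 stood at -0.064 on replicate 2 against -3.70 to -2.40, and RN-tre at -5.45 on replicate 4 against -2.19 to -0.84. In TD against V(wg) cells vg stood at 5.17 on replicate 4 against 3.24 to 3.37. In regenerating fragments Cpr51A stood at 3.86 on replicate 2 with 4.54 on the others, Thor at 4.91 on replicate 4 against 3.83 to 4.01, and Hsp83 at -1.07 on replicate 1 against -3.85 to -3.51.

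The dorsal-ventral ratio differed by limma between Wg-expressing and wild-type discs for opa by -2.78 (0.10 against 2.88), for NetA by -2.98 (-1.93 against 1.05) and for Doc3 by -1.37 (-0.05 against 1.32). It differed for fz3 by 1.83 (-0.63 against -2.46), for vir-1 by 1.91 (-0.36 against -2.27), and for CG14598 by 2.82 and 2.74 on separate probes. For the probe named wg it differed by 2.85 (-1.16 against -4.01). The dorsal samples are also unlike here, since D(wg) cells are those remaining beside the TD cells. First and second leg discs differed in Cpr64Aa by -2.28. Spots for GFP, which no comparison uses, had an array median of up to 4.55 in TD over D(wg) cells, 4.64 in TD over V(wg) cells and 3.72 in Wg-expressing discs over the reference, where spots of an adenovirus control had medians from -0.514 to 0.673.

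On both arrays labelled TD against D(wt), genes high in Wg-expressing discs lay below 0. The GFP spots, carried by the TD cells and not by the wild-type stock per the labels, had a median of -1.91 on 1 array and -5.02 on the other, while the other TD arrays had medians of 0.71 to 4.64. A lower content of these transcripts in TD cells is argued against by the -5.02, since GFP would then lie above 0, and a dye bias by a GFP median of at least 4.51 on other arrays with TD cells as probe 2. That these 2 ratios run the other way round from their labels is a candidate explanation, which the -1.91 fits. The sign was left as labelled.

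Fat body markers lay higher in Wg-expressing than in wild-type first leg discs, with a median difference of 1.06 over the 12 tested and values of 4.30 for Lsp1gamma and 3.31 for Lsp2. Carried-over fat body may account for this, although the labels say that discs were washed to reduce it. Of the 25 markers with a probe, 2 are also in another list. A reference preparation or hybridisation that differed between slide series may as well, and 0 slide series held both kinds of disc, so these explanations cannot be told apart. A difference between the genotypes in development was not tested and stays open.

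The probes of wg disagreed in Wg-expressing samples. On the 6 arrays of Wg-expressing discs the probe named wg lay 2.01 (SD 0.216) above the other, and 0.103 (SD 0.327) above it on 20 arrays without Wg-expressing samples, a difference of 1.90 (two-sided exact permutation p = 4.34e-06, the smallest that it can give). An understatement of every change by the probe named wg is argued against by a gap of 0.53 in wild-type dorsal against ventral cells, where Wg-expressing cells had 2.72. A candidate explanation, which the 1.90 fits, is that this probe binds transcripts of the wg transgene and the other does not. It was found and tested on the same data.

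Other splits of the arrays, by turned signs or regrouping, were counted for each comparison. In some comparisons 1 split, the real one, gave as many probes, a share under 0.05. They were wing against leg discs (301 probes, highest other 175 of 100 splits), Wg-expressing discs against the reference (2587, highest other 1425 of 32), Wg-expressing against wild-type first leg discs (518, highest other 185 of 100), fragments against wild-type first leg discs (755, highest other 303 of 35) and Wg-expressing discs against fragments (1046, highest other 454 of 100). The shares were not adjusted over the comparisons and were looked at after the results, so they do not exclude chance. Regrouping does not separate the kind of disc from the slide series where Wg-expressing discs are set against wild-type first leg discs or fragments. Nor does it separate regeneration from leg segment and culture where fragments are set against wild-type first leg discs. The splits are too few for a share under 0.05 in the other comparisons. There the real and highest other counts were 1412 and 547 for wild-type first leg discs, 1640 and 13 for TD against D(wg) cells, 1171 and 176 for TD against V(wg) cells, 25 and 0 for D(wg) against V(wg), 50 and 0 for D(wt) against V(wt), 1579 and 749 for fragments against the reference, and 8 and 0 for the dorsal-ventral difference. They were 1 and 2, 0 and 4, and 0 and 1 for the leg segments 1 against 2, 1 against 3 and 2 against 3, where 3, 10 and 10 of 10 splits gave as many.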

How the results depend on the processing

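The alternatives reported here were planned before the data were examined, apart from the sign turned on the arrays of TD against D(wt) and the arrays of wing against leg discs left out in turn, which were chosen after results were seen. Scaled spread was planned, but the function used for it was chosen after the planned one had failed. No paired analysis was possible beyond the pairing of both samples on an array, because the labels carry no replicate numbers that link arrays. Of 252 gene values named, 197 passed, and 150 of these stayed past the threshold with the same direction in every setting that tested them other than the sign turns, or 165 where arrays left out are not counted. Counts of calls are given below where a setting moved them by more than 1.5 times, with the lowest and highest where single arrays were left out, and the cause was not tested unless given.

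On each comparison's own arrays without the dye term, the number of probes called was 422 in wild-type first leg discs, 385 in TD against V(wg) cells, 5 in D(wg) against V(wg), 1518 in TD against D(wt), 223 in D(wt) against V(wt), 426 in fragments, 270 in Wg-expressing against wild-type discs, 177 in fragments against wild-type discs, 660 in Wg-expressing discs against fragments, 15 in the dorsal-ventral difference, 0 in leg segment 1 against 2 and 1 in leg segment 1 against 3. With scaled array spread it was 848 in wild-type first leg discs, 619 in wing against leg discs, 9 in D(wg) against V(wg), 165 in D(wt) against V(wt), 514 in fragments, 260 in Wg-expressing against wild-type discs, 116 in fragments against wild-type discs, 331 in Wg-expressing discs against fragments, 54 in the dorsal-ventral difference, 3 in leg segment 1 against 2 and 3 in leg segment 2 against 3. Without the dye term it was 11 in D(wg) against V(wg). With values required on every array, which tests fewer probes, it was 179 in wing against leg discs and 0 in leg segment 1 against 2. With the probes of a gene averaged it was 13 in D(wg) against V(wg), 5 in the dorsal-ventral difference and 0 in leg segment 1 against 2. Leaving out 1 array gave 334 to 1648 in wild-type first leg discs, 232 to 709 in Wg-expressing against wild-type discs, 491 to 959 in fragments against wild-type discs, 0 to 2 in leg segment 1 against 2, 0 to 2 in leg segment 1 against 3, 0 to 2 in leg segment 2 against 3, 1625 to 2554 in Wg-expressing discs, 473 to 1153 in TD against D(wg) cells, 577 to 1074 in TD against V(wg) cells, 11 to 322 in D(wg) against V(wg), 4 to 11 in the dorsal-ventral difference, 82 to 195 in TD against D(wt) and 19 to 35 in D(wt) against V(wt). Wg-expressing discs had 1625 without replicate 1, TD against D(wg) cells 473 and 601 without replicates 2 and 3, TD against V(wg) cells 577 without replicate 1, D(wg) against V(wg) 11 without replicate 2 and 322 without replicate 3, and D(wt) against V(wt) 19 and 20 without replicates 2 and 3. Wild-type first leg discs had 335 and 334 without replicates 1 and 2, the Wg-expressing against wild-type discs 232 and 264 without these, and the fragments against wild-type discs 491 without replicate 1 of the wild type and 493 without replicate 3 of the fragments. For leg segments 1 against 2, the 1 call ended without replicate 2, 3, 4, 7 or 8 of wing against leg discs and 2 probes passed without replicate 1. For 1 against 3, 1 probe passed without replicate 1 and 2 without replicate 9, and for 2 against 3, 2 passed without replicate 5. Where limma called 0 for a leg segment with an array left out, 35 to 155 probes had an unadjusted p under 0.05, and 29 to 82 did in the other settings with 0 calls for segment 1 against 2. In the dorsal-ventral difference 4 and 5 probes passed without replicates 1 and 2 of D(wt) against V(wt). With an estimated correlation, the lists called were 1 of 3 in wild-type first leg discs, 3 of 8 in wing against leg discs, 0 of 3 in Wg-expressing discs, 0 of 4 in TD against D(wg) cells, 3 of 12 in TD against V(wg) cells, 0 of 5 in D(wg) against V(wg), 0 of 2 in TD against D(wt), 3 of 5 in D(wt) against V(wt), 0 of 2 in fragments, 1 of 6 in Wg-expressing against wild-type discs, 0 of 1 in fragments against wild-type discs, 0 of 4 in Wg-expressing discs against fragments, 1 of 4 in the dorsal-ventral difference, 0 of 1 in leg segment 1 against 2, 1 of 3 in leg segment 1 against 3 and 0 of 3 in leg segment 2 against 3. Among genes at an unadjusted p under 0.05, 3 overlaps had a p under 0.05 in the Fisher exact test that had not passed, with odds ratios of 0.72 for TD against D(wg) cells with Wg-expressing discs, lower in both, 0.431 for TD against V(wg) cells with fragments, higher in both, and 0.544 for genes higher in TD than in V(wg) cells and lower in wing discs. These p-values were not adjusted.

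With the sign turned on the arrays whose first-named sample is probe 2, categories that hold both orientations average out by construction. Both arrays of TD against D(wt) have TD cells as probe 2, so their direction is turned by construction. The dye term stayed in the fit and takes up effects of other categories. Ilp8 in TD against D(wt) thus stood at 11.61, against 6.66 with these arrays alone turned. The number called was then 110 in wild-type first leg discs, 0 in wing against leg discs, 0 in Wg-expressing discs, 0 in TD against D(wg) cells, 0 in TD against V(wg) cells, 1 in D(wg) against V(wg), 400 in TD against D(wt), 0 in D(wt) against V(wt), 8 in fragments, 0 in Wg-expressing against wild-type discs, 5 in fragments against wild-type discs, 0 in Wg-expressing discs against fragments, 0 in the dorsal-ventral difference and 0 in leg segment 1 against 2. Where limma called 0, between 79 and 1274 probes had an unadjusted p under 0.05. With effects averaged out or taken up by the dye term, the sign that remains says little on the direction of a gene. The estimates of these genes changed sign, in part to values near 0. In wild-type first leg discs stau (-0.082), COX7C (-0.93), RpS9 (-0.88), SNRPG (-0.43), Lsp1gamma (2.14), Mhc (0.36), Lsp2 (0.96) and Fbp2 (1.12) did. In wing against leg discs Cpr78E (-0.46), pxb (0.012), Wnt6 (0.17) and sc (0.034) did. In Wg-expressing discs Reepl1 (-0.28), w (-0.36), t (-0.11), Cyp18a1 (-0.23), Spn47C (-0.18), Culd (-0.43), Lcp1 (0.61), drl (0.14), Imp (0.014), RN-tre (0.81), Act57B (0.20), Doc1 (0.59), Doc2 (0.061), sc (0.18) and phyl (0.005) did. In TD against D(wg) cells Spn47C (-0.10) and lost (-0.16) did. In TD against V(wg) cells Ilp8 (-0.72), Cyp18a1 (-0.077), upd1 (-0.074), nAChRbeta3 (-0.37), Spn47C (-0.098), Ama (-0.025), St2 (0.22), spirit (0.17), Dll (0.012), Ser (0.017), Mmp1 (-0.044), exd (-0.24), Prim1 (-0.14) and Ns1 (-0.66) did. In D(wg) against V(wg) Tfb4 (-0.33), Pu (-0.19), wg (0.97), Wnt6 (0.37), lbl (0.17) and mth (0.51) did. In TD against D(wt) ImpE2 (-4.89), Obp56a (-3.22), Obp99a (-4.53), drl (-2.76), w (8.88), Ilp8 (11.61), Reepl1 (5.79), t (5.98) and E(spl)m7-HLH (-2.13) did. In fragments Cpr51A (-0.17), Thor (-0.22), Aldh (-0.28), regucalcin (-0.068), heca (-0.72), Phk-3 (-0.35), ImpE2 (0.43), Hsp83 (0.58), wbl (0.10), mnd (0.18) and pit (0.34) did. In Wg-expressing against wild-type discs Cyp18a1 (-1.79), Cralbp (-0.93), Hph (-0.44), yellow-e3 (-0.73), RN-tre (2.01), Imp (0.32), heca (0.88), NetA (0.011), Lsp1gamma (-1.94), Fbp2 (-0.45), dpn (0.17), phyl (0.36) and Brd (1.81) did. In fragments against wild-type discs regucalcin (-0.67), Nelf-A (-1.07), Mef2 (-0.71) and san (0.45) did. In Wg-expressing discs against fragments mnd (-0.30), HnRNP-K (-0.94), Sps1 (-0.031), Cpr51A (0.59), heca (0.54), Aldh (0.11) and regucalcin (0.22) did. With the sign turned on the arrays of TD against D(wt) alone, their direction reversed by construction. In TD against D(wt) ImpE2 (-3.39), Obp56a (-2.88), Obp99a (-3.29), drl (-2.69), w (6.57), Ilp8 (6.66), Reepl1 (3.96), t (3.90) and E(spl)m7-HLH (-1.66) did.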

Other observations

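The gene lists here were written before the data were examined and chosen for description after their results were seen. Markers of neurons and sense organs were lower in wing than in leg discs, with 4 of 13 measured genes lower and none higher, or 5 adjusted over the list alone. They included the proneural genes sc (-1.16 ± 0.18, SE) and ac (-0.61 ± 0.14), phyl (-1.20 ± 0.22) and Brd (-0.92 ± 0.25), and the limma list test gave adjusted p = 0.0174 (adjusted p = 0.204 with an estimated correlation). The ac call ended on the slides of 1 series (-0.63) and the Brd call with the slide series as a covariate (-0.81) or without replicate 1, 5, 8 or 9 (-0.89 to -0.75). In Wg-expressing discs against the reference 8 of 28 were lower and none higher, the same adjusted over the list alone, with sc at -1.36 ± 0.22, l(1)sc at -0.82 ± 0.14 and phyl at -0.78 ± 0.19 (adjusted p = 0.00366 for the list, and adjusted p = 0.423 with an estimated correlation). Against wild-type first leg discs 5 of 18 were lower and none higher, or 6 adjusted over the list alone, with phyl at -1.45 ± 0.31, Brd at -2.04 ± 0.54 and l(1)sc at -1.03 ± 0.23 (adjusted p = 0.000717 for the list, and adjusted p = 0.108 with an estimated correlation). The Brd call ended without replicate 1 or 2 of the wild-type discs (-1.74 and -1.77) or replicate 6 of the Wg-expressing discs (-1.86), and that of l(1)sc without replicates 2 or 4 of the wild-type (-0.91 and -0.87) or 3 or 6 of the Wg-expressing discs (-1.02 and -0.95). With scaled spread the calls of phyl (-1.30), Brd (-1.61) and l(1)sc (-0.92) all ended.

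The list of 14 markers of the myoblasts that lie on the discs holds vg and was also tested without it, a test chosen after the result was seen. Of these 14 genes 2 were higher in wing discs and none lower, or 4 adjusted over the list alone, vg and Him (1.06 ± 0.12), while twi stood at 0.64 ± 0.19 and narrowly missed the threshold (adjusted p = 0.0502). It passed without the dye term (0.65), on these arrays alone without the dye term (0.65), as deposited (0.65), with scaled spread (0.78), with averaged probes (0.64) and with the slide series as a covariate (0.72), and without replicate 3 (0.77). vg, the largest of them, is also the wing selector gene. The list was higher with it (adjusted p = 0.000253, and adjusted p = 0.0527 with an estimated correlation). Without vg it ran in the same direction and narrowly missed the threshold (adjusted p = 0.0526, and adjusted p = 0.453 with an estimated correlation). Whether the other myoblast markers are higher in wing discs is therefore not settled. In TD against V(wg) cells 6 of 27 genes of JNK signalling and the wound response were higher and 1 lower, the same adjusted over the list alone, with Ilp8 at 5.91 ± 0.79, Mmp1 at 2.33 ± 0.25, the cell death gene rpr at 1.18 ± 0.21 and egr, a ligand of the pathway, at -1.25 ± 0.20 (adjusted p = 0.0131 for the list, and adjusted p = 0.227 with an estimated correlation). Of 12 JAK/STAT genes 3 were higher and 1 lower, or 4 and 1 adjusted over the list alone, with upd1 at 3.93 ± 0.33, zfh2 at 0.88 ± 0.22 and upd2 at 0.39 ± 0.10 (adjusted p = 0.0294 for the list, and adjusted p = 0.259 with an estimated correlation). The upd2 call ended without replicate 2 or 3 (0.36 both times) and that of zfh2 without replicate 4 (0.70), and both ended on these arrays alone without the dye term (0.42 and 0.92). Cytosolic ribosomal protein genes were lower in TD than in V(wg) cells, 10 of 86 with none higher, or 7 adjusted over the list alone (adjusted p = 1.96e-05, and adjusted p = 0.611 with an estimated correlation), and in Wg-expressing than in wild-type first leg discs, 15 of 83 with none higher, or 36 adjusted over the list alone (adjusted p = 1.75e-13, and adjusted p = 0.477 with an estimated correlation).

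Replicate 4 of the wild-type first leg discs held w at 4.94, Reepl1 at 4.10, t at 3.23 and Hsp22 at 3.37, and correlated with the other 3 arrays across probes at 0.235, 0.302 and 0.217, where these correlated with each other at 0.519 to 0.725. It is the only array of this category with the wild-type disc as probe 1 and the only one of its slide series, and the cause of its low correlation was not tested. w, Reepl1 and t are also high in Wg-expressing discs, but other values of this array lie with the wild type. The probe named wg lay at -0.167 from the other, where Wg-expressing discs had 1.71 to 2.25. Cyp18a1 stood at 0.24, where Wg-expressing discs had 3.12 to 4.98, and Lsp1gamma at -3.50, where they had -0.12 to 0.64. Whether the label of this array is right is not settled here. Without it 1648 probes passed in place of 1412. The description of replicate 3 names the slide of replicate 2, whose values differ from it (correlation 0.519), and which slide is meant is not given in the sources used here. All 4 arrays enter every value of the wild-type first leg disc. Replicate 4 of the regenerating fragments held w at 6.57. Among the 6 Wg-expressing discs Hsp22 stood at 5.37, 6.19 and 5.50 on replicates 1, 4 and 5 and at 0.42, -1.70 and -0.72 on the others, and Hsp68 at 5.13, 6.60 and 5.32 and at -0.10, -1.57 and -0.89. Ilp8 stood at 3.92, -1.65 and 7.15 on the arrays of D(wg) against V(wg). GFP spots gave a median of -0.75 over 2 spots on replicate 1 of D(wt) against V(wt).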
